A study of Mus musculus with 15 samples.

How the data were processed

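Liver RNA from single mouse fetuses and newborns was hybridised to Agilent 1-colour whole-genome expression arrays, with 1 array per sample and 15 arrays in all. The labels give 4 groups from 2 genotypes and 2 ages: wild type (WT) and mice whose maternal chromosome lacks the miR-379/miR-410 microRNAs (KO), at embryonic day 19.5 after caesarean section (E19.5) and on postnatal day 0 after natural delivery (P0). Total RNA was extracted with Tri-reagent, its integrity was read on a Bioanalyzer, and the RNA was labelled with Cy3 for low input, per the labels. The groups held 3 arrays (WT_E19), 3 arrays (KO_E19), 4 arrays (WT_P0) and 5 arrays (KO_P0). The arrays lay on 3 slides. Slide 1 held E19.5 arrays only, slide 2 held all 4 groups and slide 3 held P0 arrays only, and each slide was also 1 scan.

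The deposited array files give, per the file headers, a fluorescence intensity for each spot from Agilent Feature Extraction 10.10. The processed signal is an intensity that the authors' software had corrected for background and for trends across the array, with no step between arrays. The same deposited files give the mean and the local background intensity of each spot, and other columns with 0 or 1 marks for spots well above background, saturated spots and non-uniform or population outliers. The authors also deposited a series table of log2 values, which per the submitters' processing notes came from Feature Extraction and limma. Every column of that table had the same median, 7.86, and across probes it correlated with the log2 mean signal of its array at r from 0.9992 to 0.9999 and with the log2 processed signal at r from 0.9874 to 0.9908. The table held 35951 probes with 80 empty cells, and its background and filter steps are not given in the sources used here.

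Each array had 59305 non-control spots and 3671 control spots, and 55681 non-control probes. The values analysed were log2 processed signal minus the array's 75th percentile over non-control spots, so 0 stands for the 75th percentile of that array. Outlier spots, 146 to 212 per array, were set to missing, and spots of a probe were averaged. A probe was kept when it was well above background on at least 3 arrays of at least 1 group, which left 34408 probes, 33027 of them with a gene name. The 2744 probes named only by a probe ID were left out of gene counts. The brightest probe stood for each gene name, which gave 22638 tested genes or named transcripts, of which 3304 are long noncoding RNA probes named by position. RefSeq accessions matched 15335 names, and 1585 of these have another current symbol. Names are printed as on the array, with the current symbol once where it differs. The brightest probes responded little to array brightness: over the 15 arrays the median slope of log2 signal on the 75th percentile was 0.22 for the 54 genes with a mean log2 signal over 18, against 1 for those from 8 to 16. Differences of such genes, among them Alb and Fgb, may follow brightness. Probe positions are on mm9, and exons, introns and untranslated regions were not given in the sources used here. Probes of close paralogs (globins, trypsins, Cyp4a, Serpina and immunoglobulin genes) may hybridise with more than 1 transcript.

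Genes were tested with limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8) for reading. lmFit and eBayes were run on 1 model of 4 group means over all 15 arrays, with 11 residual and 2.5 prior degrees of freedom, and 5 contrasts: KO minus WT at E19.5 and at P0, P0 minus E19.5 in WT and in KO, and the difference of the KO effect between the ages. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, with no fold limit, and all p-values are 2-sided unless stated. Errors of log2 differences are limma standard errors (SE), and ± gives the SD between arrays. For a gene below background on every array of a group, the fold is given as a lower bound, with the gene's level on each array of that group set to its own value or to the dimmest value above background on that array, whichever is higher. Such a bound holds for the processed signal only, and with other background corrections the fold can be smaller.

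Before the data were examined, 43 lists with 602 entries were fixed from textbook knowledge. They cover metabolic pathways, liver maturation, growth, stress, signalling, proliferation, imprinting, the deleted domain, blood and liver cell types, other tissues near the liver, and sex. The 42 lists other than the sex-linked one were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists. Each call was set beside camera with an estimated correlation and beside fry, and members were also counted with p-values adjusted over the list alone. Named genes follow a rule fixed at the same time: per contrast, the 8 largest rises and 8 largest falls among genes that passed and whose 2 groups did not overlap, without names that are only clone or prediction IDs, plus up to 3 members per list with the smallest p to about 30 genes, plus all measured genes of the deleted domain, and the 5 smallest p-values where no gene passed. A gene outside the rule is marked as chosen after its values were seen. Results of 2 genes that are counted in the totals are not reported here.

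The procedure was tested on simulated data with the same groups, in which 67, 67 and 66 genes were changed by 1.5-fold, 2-fold and 4-fold. The mitochondrial fatty acid oxidation list was lowered as well. Noise was drawn independently for each gene and array, without structure by slide, pair, brightness or other tissues. Recovery and false calls on the real arrays may therefore differ from those given here. At P0 it recovered 43.3%, 77.6% and 100% of them for KO minus WT, at E19.5 17.9%, 55.2% and 86.4%, and for the difference of effects 3%, 35.8% and 89.4%. It gave 0 calls with the wrong sign. Among the unchanged genes, 9 (E19.5), 7 (P0), 4 (WT over age), 8 (KO over age) and 6 (difference) were called. The number of arrays limits the precision, and no interval from counts applies.

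Replicate numbers were checked as possible pairs. Across genes, residuals of WT and KO arrays with the same number at P0 correlated at r of 0.14, 0.2, 0.13 and 0.27, so 4 pairs were treated as possible pairs, each within 1 slide, and a fit with the replicate block is given beside the P0 results. WT_P0 3 correlated more with KO_P0 4 (0.25) than with its own number, and KO_P0 5 had no partner. At E19.5 the r values were 0.21, 0.01 and 0.14, and the numbers were not read as pairs. Other alternatives fixed before the data were examined were quantile normalization, centring on the median, normexp background correction (offset 50) with 75th percentile scaling or quantile normalization, the authors' series table, filters on dim probes, ways to combine probes, slide as a block or alone, a sex covariate, leaving out each array in turn, other limma settings (trend and robust, array weights, treat at 1.2-fold, a 2-fold limit, the groups of a contrast alone) and a plain two-group test. Added after the data were seen were fits without WT_P0 3 and 4, which carried pancreatic transcripts, without the 5 arrays with raised muscle or adrenal transcripts (WT_E19 1, WT_P0 1, 2 and 4, KO_P0 5), and with each array's 75th percentile as a covariate (brightness covariate). Without WT_P0 3 and 4, the WT_P0 arrays lay on slide 2 only and the KO_P0 arrays on slides 2 and 3, which mixes genotype with slide. Without the 5 arrays, WT_P0 3, a pancreatic array, was the only WT_P0 array. Calls from that fit are therefore not given for contrasts with WT_P0. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

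Sites for the deleted microRNAs were not searched, because untranslated regions were not given in the sources used here, and mature microRNAs are not measured by these probes. Sex was read from sex-linked transcripts and was not balanced: WT_E19 held 2 female and 1 male pups, KO_E19 1 and 2, WT_P0 3 and 1, KO_P0 2 and 3. Age and mode of delivery changed together and cannot be told apart in this design.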

Results

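Liver transcripts were measured on 15 arrays from wild-type (WT) mouse fetuses and newborns and from littermates that lacked the miR-379/miR-410 microRNA cluster on the chromosome from their mother (KO), all C57BL/6J. The groups were WT_E19 (n = 3) and KO_E19 (n = 3), taken by caesarean section at E19.5, and WT_P0 (n = 4) and KO_P0 (n = 5), taken after natural delivery at P0. Signal strength differed between the groups: the 75th percentile of log2 signal was 8.52 ± 0.07 (SD, n = 3) in WT_E19, 8.93 ± 0.12 (n = 3) in KO_E19, 9.44 ± 0.17 (n = 4) in WT_P0 and 9.16 ± 0.1 (n = 5) in KO_P0. Of its variance, 89.8% lay between groups. Between 53.1% and 65.7% of probes were above background on an array, 0 spots were saturated, and the number of arrays limits the precision of each value. Levels below are log2 relative to each array's 75th percentile, on which 22638 genes or named transcripts were tested. Transcripts typical of other tissues were raised on some arrays. The median of the exocrine pancreas list was 1.27 on WT_P0 3 and 2.87 on WT_P0 4, with the other 13 arrays between -3.07 and -1.03. The adrenal cortex list had a median of 2.02 on WT_P0 2, against -0.5 or lower elsewhere. Skeletal muscle transcripts were raised on WT_E19 1 (-0.93), WT_P0 1 (-1), WT_P0 2 (-0.69), WT_P0 4 (0.8) and KO_P0 5 (0.1), with the other arrays between -4.37 and -2.42.

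**Figure D1:**
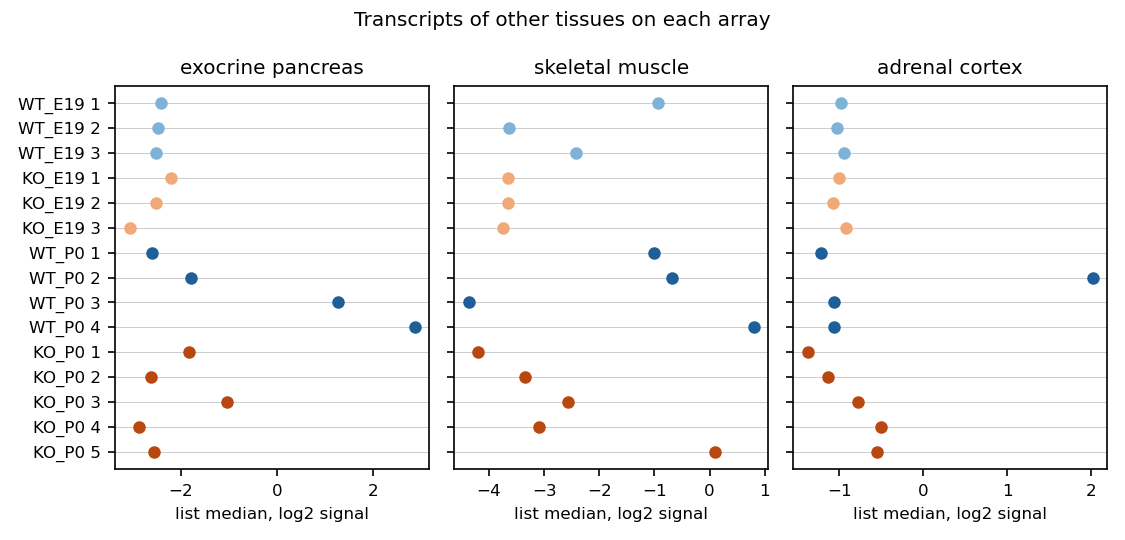
Median log2 signal of the lists of exocrine pancreas (12 measured members), skeletal muscle (11) and adrenal cortex (7) transcripts on each of the 15 arrays, as points coloured by group, with 0 at each array's 75th percentile. Pancreatic transcripts stand apart on WT_P0 3 (1.27) and WT_P0 4 (2.87), and adrenal transcripts on WT_P0 2 (2.02).

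Mirg, the noncoding host transcript of the cluster's microRNAs (probe on mm9 chromosome 12, 110987569 to 110987628), was measured first as a check of the genotype labels. It was 11.2-fold lower in KO liver at E19.5 (log2 -3.48, SE 0.28, adjusted p = 0.00017), with levels of 2.14 ± 0.24 (n = 3) in WT_E19 and -1.34 ± 0.22 (n = 3) in KO_E19. At P0 it was 6.49-fold lower (log2 -2.70, SE 0.23, adjusted p = 0.00012), with 1.45 ± 0.32 (n = 4) in WT_P0 and -1.25 ± 0.48 (n = 5) in KO_P0. With the brightness covariate the E19.5 difference was -2.84 and no longer passed (adjusted p = 0.05). Each KO array was below each WT array, and the probe stayed above background on all 15 arrays. Of the other genes of the Dlk1-Dio3 imprinted domain, which holds the cluster, Begain fell at P0 (-0.63, SE 0.13, adjusted p = 0.012), a call that ended with the replicate block (adjusted p = 0.074) and without WT_P0 3 and 4 (0.12). Begain differed by -0.18 at E19.5. The KO minus WT differences of Meg3 (0.16 at E19.5 and -0.08 at P0), Dlk1 (0.41 and 0.30), Dio3 (-0.03 and 0.72) and Dio3os (0.07 and 0.03) did not pass. Neither did 6430411K18Rik, which was not well above background on any KO array. At P0, 2 of 7 measured genes of the list passed over all genes, and with p-values adjusted over the list alone 1 was higher and 3 were lower. Rian was not found by name, and the ends of the deletion are not given in the sources used here.

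**Figure D2:**
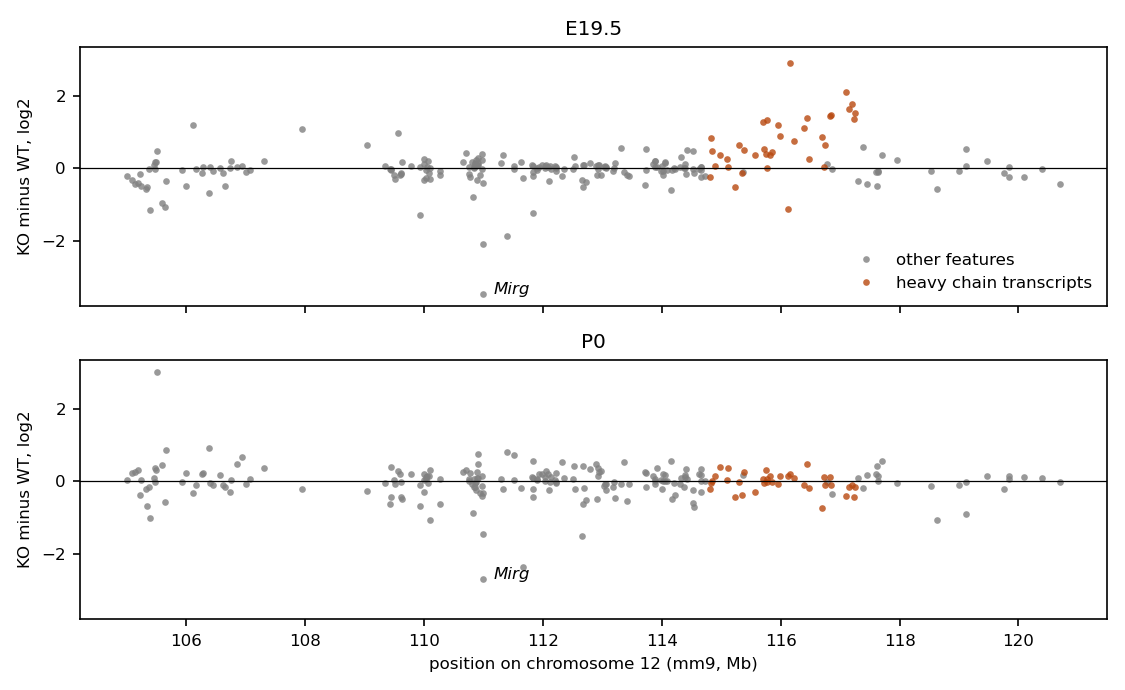
KO minus WT difference in log2 signal (vertical axis) of tested features by position on distal chromosome 12 (horizontal axis, mm9, Mb) at E19.5 (top) and P0 (bottom), with 1 point per gene or transcript. Mirg lies lowest at both ages (-3.48 and -2.70), and immunoglobulin heavy chain transcripts, in colour, have a median of 0.63 at E19.5 and -0.02 at P0.

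The comparison of KO and WT at E19.5 asks what the deletion changes in fetal liver before birth. Cyp2e1, a cytochrome P450 of mature liver, fell by 1.75 on the log2 scale (SE 0.21, adjusted p = 0.008), from 6.21 ± 0.27 (n = 3) to 4.46 ± 0.15 (n = 3). Hsd17b6, a hydroxysteroid dehydrogenase, fell by 1.83 (SE 0.23, adjusted p = 0.0084) and Acnat2, a peroxisomal acyl-CoA amino acid acyltransferase, fell by 1.68 (SE 0.24, adjusted p = 0.019). In all, 8 of 22638 genes passed, 3 higher and 5 lower in KO, all of them at least 2-fold, and 628 had an unadjusted p under 0.05 where chance gives 1132. These counts rest on 1 estimate of spread shared with the P0 arrays. A count under that of chance therefore does not mean that the genotypes differed less than by chance. In a plain two-group test more genes had an unadjusted p under 0.05 and fewer passed, as given in the section on processing. The other 4 genes that passed, which are outside the naming rule and were chosen after their values were seen, are a long noncoding RNA probe beside Mirg (-2.09) and 3 transcripts that rose. All 3 are from the immunoglobulin heavy chain interval of chromosome 12: ENSMUST00000103538 (1.46), LOC100505009 (1.53) and ENSMUST00000103515, which was below background on the WT_E19 arrays and at -3.36 ± 0.21 in KO_E19 (n = 3). Ces3a, a carboxylesterase (-1.56, SE 0.27, adjusted p = 0.15), and Fgf21, a hepatic hormone induced by fasting (-2.68, SE 1.07, adjusted p = 1), did not pass.

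At E19.5, 14 of 42 gene lists passed camera, 4 up and 10 down, and 0 did with an estimated correlation (smallest adjusted p = 0.11). The shifts were small. Hepatocyte secreted proteins had a median of -0.22, with 0 of their members passing over all genes, 7 lower when adjusted over the list alone and examples in Fgb (-0.37), Fgg (-0.35) and Alb (-0.32); the list's adjusted p was 3.8e-12, and 0.11 with an estimated correlation. That shift was -0.02 and did not pass with quantile normalization (adjusted p = 0.27), normexp and quantile (0.34) or the authors' value table (0.46). The cytochrome P450 drug metabolism list had a median of -0.14, with 1 member lower (Cyp2e1), 2 when adjusted over the list alone, and adjusted p = 0.00015 (0.36 with an estimated correlation); it ended with normexp and 75th percentile (0.27). The IGF and growth hormone axis list had a median of -0.13 (adjusted p = 0.0066, and 0.11 with an estimated correlation), with Igf1 at -0.72, not passing, and ended with normexp and 75th percentile (0.71). Interferon response transcripts had a median of 0.30 (adjusted p = 0.0096, and 0.82 with an estimated correlation), ending without WT_E19 1 (0.091) or WT_E19 2 (0.05). Cell cycle transcripts had a median of 0.11 (adjusted p = 0.0091, and 0.82 with an estimated correlation), ending without WT_E19 1 (0.37) or KO_E19 3 (0.11) and with quantile normalization (0.086). Mitochondrial fatty acid oxidation (-0.04, adjusted p = 0.15) and erythroid cells (0.08, adjusted p = 0.98) did not pass. Skeletal muscle transcripts had a median of -1.29 (adjusted p = 0.0015, and 0.72 with an estimated correlation), and without WT_E19 1 the median was -0.61 (0.1).

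At E19.5, with slide as a block 7 genes and 12 lists passed, and within slide 2, which holds 2 arrays of each of these groups, 1 gene and 10 lists. Of the 14 lists, 12 and 9 passed there in the same direction. With slide as a block the call of Acnat2 ended (adjusted p = 0.076). The calls were 0 higher and 6 lower with normexp and the 75th percentile, 7 and 7 with normexp and quantile, and 7 and 6 from the authors' table. Without 1 array, the count was 5 (WT_E19 2), 4 (KO_E19 1) or 3 (KO_E19 3). Cyp2e1 no longer passed without KO_E19 1 (0.055) or KO_E19 3 (0.073), Hsd17b6 without KO_E19 3 (0.078), and Acnat2 without any 1 of the 6 arrays (0.05 to 0.16). The calls of Cyp2e1 and Hsd17b6 also ended within slide 2 (both 0.35), with the replicate block (both 0.082) and without the 5 arrays with muscle or adrenal transcripts (0.17 and 0.23), and that of Hsd17b6 with the brightness covariate (0.13). That of Acnat2 ended within slide 2 (0.33), with the replicate block (0.26) and with the brightness covariate (0.52).

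The comparison at P0 asks what the deletion changes in newborn liver, after the switch from placental supply to milk and stored fuel. Cyp2e1 was 7.68-fold lower in KO liver (log2 -2.94, SE 0.18, adjusted p = 4.9e-06), at 7.35 ± 0.26 (n = 4) in WT_P0 and 4.41 ± 0.33 (n = 5) in KO_P0. Cyp1a2, another P450 of mature liver, fell by 3.90 (SE 0.64, adjusted p = 0.0047), from -2.06 ± 1.36 (n = 4) to -5.96 ± 0.92 (n = 5), and was above background on 1 of the 5 KO_P0 arrays. It was at -3.31, -3.06, -0.47 and -1.42 on WT_P0 1 to 4. Without WT_P0 3 and 4 its call ended, and the smallest fall of Cyp1a2 over 30 alternatives was -1.53. Hadh, an enzyme of fatty acid oxidation, fell by 0.90 (SE 0.15, adjusted p = 0.0054), and Fgf21 fell by 3.22 (SE 0.88, adjusted p = 0.044). Fgf21 was at -6.78 on KO_P0 5 and between -3.29 and -2.73 on the other KO_P0 arrays. Its smallest fall over 30 alternatives was -1.94. Mt1, a glucocorticoid-responsive metallothionein, rose by 1.00 (SE 0.22, adjusted p = 0.018). In all, 1591 of 22638 genes passed, 521 higher and 1070 lower in KO_P0, of which 371 differed at least 2-fold (85 higher and 286 lower). An unadjusted p under 0.05 was found for 5506 genes, where chance gives 1132. These counts rest on 1 estimate of spread shared with the E19.5 arrays. With only the P0 groups, and in a plain two-group test, far fewer genes passed, as given in the section on processing.

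Mitochondrial fatty acid oxidation at P0 had a median of -0.56. Of its 17 measured members 8 fell, 0 rose and 9 did not pass, and 16 were lower when adjusted over the list alone. Hadh went from 4.92 ± 0.34 (n = 4) to 4.01 ± 0.19 (n = 5), and the β-oxidation enzymes Eci1 (-0.70, SE 0.12, adjusted p = 0.0067) and Decr1 (-0.61, SE 0.1, adjusted p = 0.0045) also fell. The list's adjusted p was 9.7e-11, and 0.22 with an estimated correlation. Its median was -0.56 with slide as a block, -0.22 within slide 2 (adjusted p = 0.027), -0.82 within slide 3 and -0.46 with the replicate block. Without WT_P0 3 and 4, the arrays with pancreatic transcripts, it was -0.32 (6.6e-05), and with the brightness covariate -0.32 (0.00052). PPARA targets and peroxisomal oxidation, genes of the fasting-activated nuclear receptor PPARA, had a median of -0.77, with 12 of 20 members lower, 1 higher and 7 not passing, and 14 lower and 1 higher when adjusted over the list alone (adjusted p = 5.3e-07, and 0.32 with an estimated correlation). Acaa1b, a peroxisomal thiolase, fell by 1.33 (SE 0.26), Vnn1, a pantetheinase, by 0.76 (SE 0.13) and Fabp1, the liver fatty acid binding protein, by 0.65 (SE 0.13), while Pdk4, chosen after its value was seen, rose by 1.02. The list's median was -0.78 with slide as a block, -0.24 within slide 2 (adjusted p = 0.35), -1.46 within slide 3 and -0.40 without WT_P0 3 and 4 (0.0078). Ketone body synthesis had a median of -0.48, with 2 of 4 members lower and 4 when adjusted over the list alone, and adjusted p = 0.00038 (0.16 with an estimated correlation). Bdh1, a ketone body dehydrogenase chosen after its value was seen, fell by 1.27 (SE 0.15, adjusted p = 0.0012), and within slide 2 the list was at -0.23 (adjusted p = 0.061). Oxidative phosphorylation, with a median of -0.16, had 3 of 25 members lower, also 3 when adjusted over the list alone (adjusted p = 0.00011, and 0.39 with an estimated correlation). Its median was -0.04 within slide 2 (0.94), -0.32 within slide 3 and -0.03 without WT_P0 3 and 4 (0.45).

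Several lists of liver function passed camera as lower at P0, and 0 of them did with an estimated correlation. The cytochrome P450 drug metabolism list had a median of -0.57 with 7 of 16 members lower and 9 not passing, 9 lower when adjusted over the list alone, and adjusted p = 5.3e-07 (0.18 with an estimated correlation). Ces3a fell by 1.59 (SE 0.22, adjusted p = 0.0024). That list was at -0.62 with slide as a block, -0.35 within slide 2 (adjusted p = 0.0055), -1.22 within slide 3 and -0.29 without WT_P0 3 and 4 (0.0062). Bile acid synthesis and transport had a median of -0.51 with 6 of 12 members lower and 1 higher, 8 and 1 when adjusted over the list alone, and adjusted p = 2e-04 (0.16 with an estimated correlation). Among these, chosen after their values were seen, the nuclear receptor Nr0b2 fell by 2.74 (SE 0.37, adjusted p = 0.0022) and the transporters Slco1b2 by 1.64 (SE 0.22, adjusted p = 0.0019) and Abcb11 by 1.25 (SE 0.18, adjusted p = 0.0026). The list's median was -0.51 with slide as a block, -0.51 within slide 2, -0.53 within slide 3 and -0.52 without WT_P0 3 and 4. Cholesterol synthesis had a median of -0.31 with 7 of 24 members lower, and 11 lower and 1 higher when adjusted over the list alone (adjusted p = 0.0021, and 0.31 with an estimated correlation). The median was -0.32 with slide as a block, -0.30 within slide 2 and -0.34 within slide 3 (adjusted p = 0.052). The IGF and growth hormone axis list had a median of -0.45 with 5 of 14 members lower and 1 higher, 9 and 2 when adjusted over the list alone (adjusted p = 0.0021, and 0.16 with an estimated correlation). In it Igfals, the acid labile subunit of IGF binding protein, chosen after its value was seen, fell by 1.10 (SE 0.19, adjusted p = 0.0064). The list was at -0.45 with slide as a block, -0.13 within slide 2 (adjusted p = 0.14), -0.59 within slide 3 and -0.29 without WT_P0 3 and 4 (0.045). Amino acid catabolism had a median of -0.36 with 5 of 18 members lower and 1 higher, 6 and 1 when adjusted over the list alone (adjusted p = 2e-04, and 0.39 with an estimated correlation). It was at -0.35 with slide as a block, 0.12 within slide 2 (0.6), -0.81 within slide 3 and -0.15 without WT_P0 3 and 4 (0.1).

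Lists of erythroid cells, cell cycle and hormone response passed camera as higher at P0, and 0 of them did with an estimated correlation. The erythroid cells list had a median of 0.41, with 4 of 27 members higher and 23 not passing, 19 higher when adjusted over the list alone, and adjusted p = 5.6e-09 (0.31 with an estimated correlation). Tspan33, an erythroid tetraspanin (0.68, SE 0.13, adjusted p = 0.0086), and Hbb-y, an embryonic β-like globin (0.88, SE 0.22, adjusted p = 0.033), rose. The cell cycle list had a median of 0.33, with 3 of 25 members higher, 15 when adjusted over the list alone, and adjusted p = 9.4e-08 (0.32 with an estimated correlation). Ccnb1, Kif20a and Mki67 each rose by 0.54 (SE 0.13 to 0.15). Within slide 2, within slide 3 and without WT_P0 3 and 4, erythroid cells were at 0.28, 0.58 and 0.18, and the cell cycle list at 0.15, 0.50 and 0.17; with slide as a block they were at 0.43 and 0.34. The glucocorticoid and cAMP response list had a median of 0.56, with 8 of 14 members higher and 6 not passing, 9 when adjusted over the list alone, and adjusted p = 4.4e-05 (0.2 with an estimated correlation). Besides Mt1, the MAP kinase phosphatase Dusp1 (0.62, SE 0.13) and glucocorticoid-induced Tsc22d3 (0.71, SE 0.16) rose, and the list was at 0.55 with slide as a block, 0.43 within slide 2, 0.49 within slide 3 and 0.52 without WT_P0 3 and 4. Gluconeogenesis did not pass as a list (median 0.19, adjusted p = 0.13), but 4 of its 13 members rose and 1 fell, 6 and 3 when adjusted over the list alone. The rises include Sds, a serine dehydratase (1.93, SE 0.32, adjusted p = 0.0049), Got1, an aspartate aminotransferase (1.57, SE 0.23, adjusted p = 0.0025), and Ppargc1a, a fasting-induced coactivator (0.93, SE 0.17, adjusted p = 0.0072), all chosen after their values were seen. Pck1 of the same list, also chosen so, was at 7.63 ± 0.1 (n = 4) in WT_P0 and 7.55 ± 0.26 (n = 5) in KO_P0. The integrated stress response list had a median of 0.37 with 3 of 15 members higher and 1 lower, 7 and 2 when adjusted over the list alone (adjusted p = 0.0068, and 0.39 with an estimated correlation). Its transcription factor Atf4, chosen after its value was seen, rose by 0.54 (SE 0.1), and the list did not pass without WT_P0 3 and 4 (0.11, adjusted p = 0.24) or with normexp and 75th percentile (0.06).

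**Figure D3:**
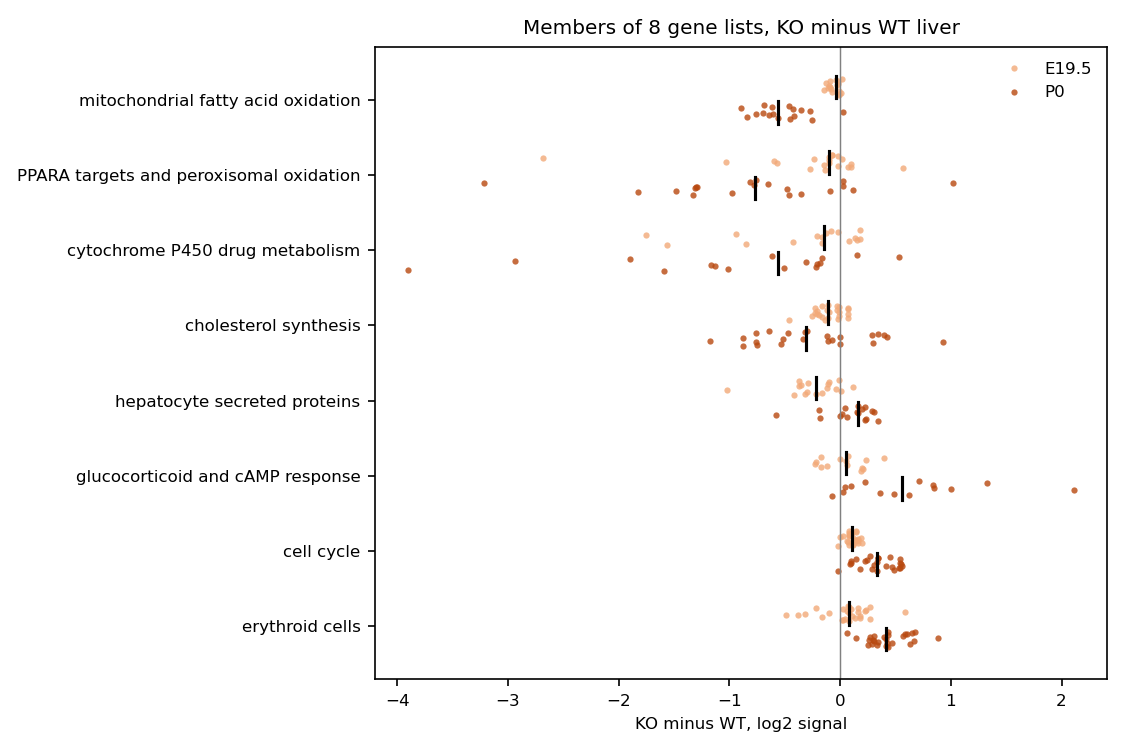
KO minus WT difference in log2 signal (horizontal axis) of the members of 8 gene lists (rows) at E19.5 (light) and P0 (dark), with 1 point per gene and a bar at the list's median. The mitochondrial fatty acid oxidation list moves from a median of -0.04 at E19.5 to -0.56 at P0, and the erythroid cells list from 0.08 to 0.41.

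Further lists passed camera at P0, and their calls, like those of amino acid catabolism, oxidative phosphorylation and the integrated stress response above, ended in several settings. The exocrine pancreas list had a median of -2.14, with 0 of 12 members passing over all genes and 11 lower when adjusted over the list alone (adjusted p = 0.00036, and 0.39 with an estimated correlation). Its median was -0.12 within slide 2 (0.6), -4.32 within slide 3 and -0.19 without WT_P0 3 and 4 (0.99). The interferon response list had a median of 0.78, with 2 of 14 members higher, 9 when adjusted over the list alone (adjusted p = 5.4e-05, and 0.39 with an estimated correlation). Its median was -0.04 within slide 2 (0.76), 1.55 within slide 3 and 0.11 without WT_P0 3 and 4 (0.54). Unfolded protein response transcripts had a median of -0.31 (adjusted p = 0.023, and 0.52 with an estimated correlation), but 0.19 within slide 2 and 0.15 without WT_P0 3 and 4 (0.26), and the call ended without WT_P0 3 (0.077), WT_P0 4 (0.42), KO_P0 1 (0.053) or KO_P0 3 (0.073). Skeletal muscle transcripts had a median of -1.26 (adjusted p = 0.03, and 0.52 with an estimated correlation), and the list did not pass without 7 of the 9 P0 arrays taken 1 at a time (0.053 to 0.19), those other than WT_P0 3 and KO_P0 5. Hepatocyte secreted proteins had a median of 0.16 (adjusted p = 0.023, and 0.39 with an estimated correlation), but -0.01 with quantile normalization (0.41) and -0.02 from the authors' value table (0.26), and the call ended without WT_P0 2 (0.063) or KO_P0 2 (0.064). Hepatocyte transcription factors had a median of -0.34 with 4 members lower and 1 higher, 6 and 2 when adjusted over the list alone (adjusted p = 0.035, and 0.26 with an estimated correlation), ending without WT_P0 1, 2 or 4 or KO_P0 5 (0.05 to 0.056). In it Cebpa, chosen after its value was seen, fell by 0.83 (SE 0.14, adjusted p = 0.0054).

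Outside the lists at P0, the largest falls were in Hsd3b4, a steroid dehydrogenase (at least 14.1-fold lower), Prok1, a prokineticin (-3.83, SE 0.57), Sult1c2, a sulfotransferase (-3.32, SE 0.58), Agtr2, the angiotensin II type 2 receptor (at least 7.96-fold lower), and Ckmt2, a mitochondrial creatine kinase (at least 7.82-fold lower). Agtr2 and Hsd3b4 were highest on WT_P0 2, the array with adrenal transcripts, at -1.63 and 0 against at most -4.01 and -2.87 on the other WT_P0 arrays. Their bounds are for the mean of the 4 WT_P0 arrays, and without WT_P0 2 they were 7.77-fold for Hsd3b4 and 4.86-fold for Agtr2. Ckmt2 was highest in its groups on WT_P0 4 (-2.78) and KO_P0 5 (-5.46), the arrays with the most muscle transcripts. With normexp and the 75th percentile the falls of Hsd3b4, Agtr2 and Ckmt2 were their smallest, -1.28, -0.64 and -0.54 on the log2 scale. These lie under the bounds, which hold for the processed signal only. The largest rises were in Ctsj, a placental cathepsin (3.07, SE 0.65), Serpina3i (3.02, SE 0.4), Fibin (2.98, SE 0.41) and Sgpp2, a sphingosine phosphate phosphatase (at least 7.04-fold higher). Next came Esrrg, an orphan nuclear receptor (2.52, SE 0.34), Tmem212 (2.33, SE 0.36), Slco4c1, an organic anion transporter (2.29, SE 0.34), and Fam134b, now Retreg1, a receptor for autophagy of the endoplasmic reticulum (2.28, SE 0.34). Their adjusted p-values lay between 0.0018 and 0.015.

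At P0, slide as a block gave 1961 genes, 1487 of them shared with the 1591, slide 2 alone 2 genes, slide 3 alone 861, and the replicate block 433 (118 higher and 315 lower, 373 shared). Without WT_P0 3 and 4, which left WT_P0 arrays on slide 2 only, the count was 168 (22 higher and 146 lower). It was 3 with the brightness covariate, 614 with median centring and 1024 with the sex covariate. Without the 5 arrays with muscle or adrenal transcripts, WT_P0 3 stood alone for WT_P0, so calls at P0 from that fit are not given. Of the 21 lists, 21 passed in the same direction with slide as a block, 13 without WT_P0 3 and 4, 10 within slide 2 and 9 with the brightness covariate. The 9 were ketone body synthesis, mitochondrial fatty acid oxidation, PPARA targets and peroxisomal oxidation, cholesterol synthesis, bile acid synthesis and transport, cytochrome P450 drug metabolism, cell cycle, glucocorticoid and cAMP response and erythroid cells. Normexp and the 75th percentile gave 928 higher and 1189 lower. The count was 585 without WT_P0 3, 633 without WT_P0 4, 1059, 1006, 958 and 1048 without KO_P0 2, 3, 4 and 5. The calls of genes chosen after their values were seen were not followed through these settings. Of the 34 genes that the naming rule gave and that passed, 33 still did with slide as a block (Fgf21 at 0.061), 15 with the replicate block and 9 without WT_P0 3 and 4. The 15 were Cyp1a2, Prok1, Agtr2, Ckmt2, Cyp2e1, Ces3a, Hadh, Vnn1, Mirg, Dusp1, Fam134b, Tmem212, Esrrg, Fibin and Serpina3i, and the other 19 had adjusted p from 0.051 to 0.13. The 9 were Prok1, Ckmt2, Cyp2e1, Mirg, Ces3a, Mt1, Tmem212, Esrrg and Serpina3i, and the other 25 had 0.051 to 0.32. Cyp2e1 was at -2.96 with slide as a block, -2.80 within slide 2, where the call ended (adjusted p = 0.081), and -3.10 within slide 3. Its smallest fall over 30 alternatives was -2.51. Single arrays ended the calls of Ctsj (without WT_P0 3, 0.059), Tsc22d3 (WT_P0 4, 0.062), Kif20a (WT_P0 3, 0.083, and WT_P0 4, 0.078). They also ended those of Hbb-y (each of 7 P0 arrays, all but WT_P0 1 and KO_P0 2, up to 0.098) and Ccnb1 (WT_E19 3, KO_E19 1 and 2, WT_P0 3 and 4 and KO_P0 2, 3, 4 and 5, up to 0.11). Calls that most arrays could end were those of Fgf21 (each array but KO_E19 2 and 3, WT_P0 1 and KO_P0 1, up to 0.13), Hbb-b1 (now Hbb-bt, each array but KO_E19 1, WT_P0 1 and KO_P0 4 and 5, up to 0.097) and Mki67 (each array but WT_P0 1 and KO_P0 4, up to 0.13).

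**Figure D4:**
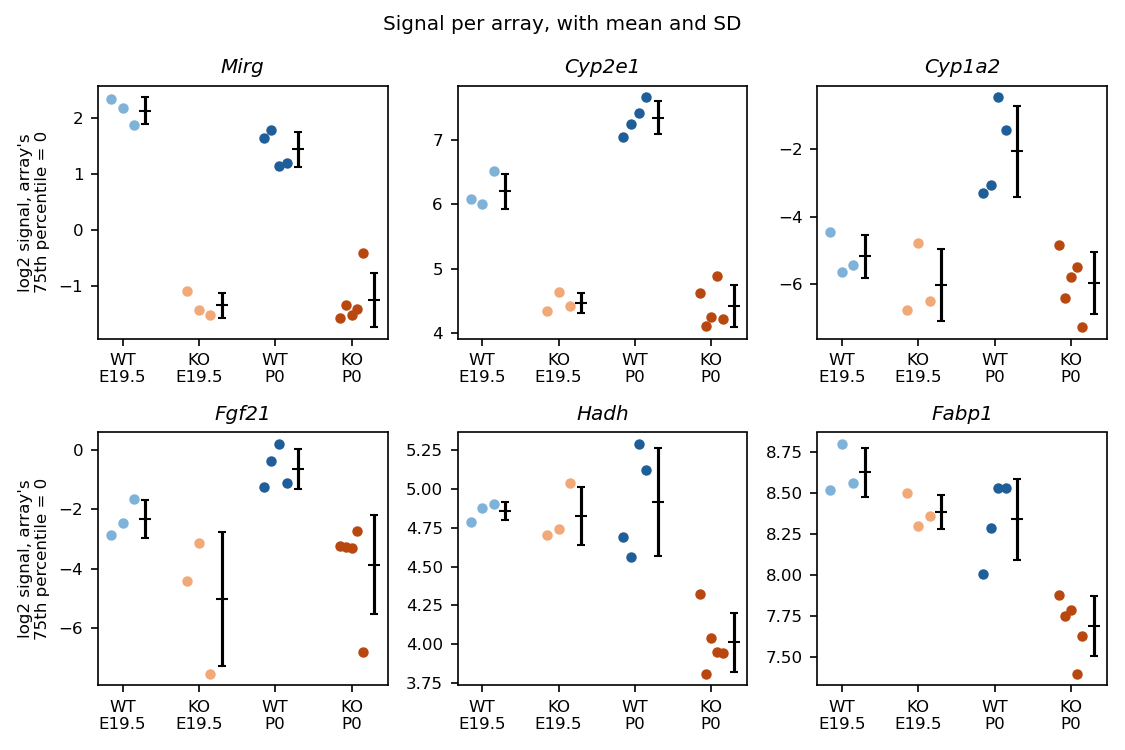
Log2 signal (vertical axis, 0 at each array's 75th percentile) of Mirg, Cyp2e1, Cyp1a2, Fgf21, Hadh and Fabp1 in the 4 groups (horizontal axis), with 1 point per array and the mean and SD beside each group. Cyp2e1 lies between 4.11 and 4.88 on the KO_P0 arrays and between 7.06 and 7.67 on the WT_P0 arrays.

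The change from E19.5 to P0 in WT liver describes the transition around birth, with age and mode of delivery changing together. Lipid synthesis fell: 23 of 24 measured members of cholesterol synthesis were lower (median -2.11, adjusted p = 1.7e-25, and 0.0025 with an estimated correlation), as were 11 of 14 of fatty acid synthesis (median -2.24, adjusted p = 1.7e-12, and 0.048 with an estimated correlation). Fasn, the fatty acid synthase, fell by 3.6 (SE 0.20, adjusted p = 5.9e-07), from 1.72 ± 0.28 (n = 3) to -1.88 ± 0.37 (n = 4), Insig1, a sterol-regulated brake on lipid synthesis, by 3.54 (SE 0.27), and Sqle, squalene epoxidase, by 2.09 (SE 0.11). Cidec, a lipid droplet protein, was at least 41.8-fold higher. The medians of both lists were -2.12 and -2.07 with slide as a block, and -1.99 and -1.95 within slide 2. In all, 4301 genes passed, 1890 higher and 2411 lower at P0, 1119 of them at least 2-fold, with 7665 at an unadjusted p under 0.05.

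In WT, 15 of 20 members of PPARA targets and peroxisomal oxidation rose and 0 fell (median 1.40, adjusted p = 5.5e-09, and 0.29 with an estimated correlation), among them the thioesterase Acot2 (2.68, SE 0.33), Angptl4 (0.79) and Eci2 (0.73). This list was at 1.43 with slide as a block and 1.18 within slide 2. Mitochondrial fatty acid oxidation had a median of 0.25 with 6 of 17 members higher (adjusted p = 0.00025, and 0.47 with an estimated correlation), and was at 0.14 within slide 2 (0.12). Gluconeogenesis had a median of 0.34 with 6 of 13 members higher (adjusted p = 5.6e-05, and 0.082 with an estimated correlation). Amino acid catabolism had a median of 0.69 with 9 of 18 higher and 1 lower (adjusted p = 9.3e-06, and 0.39 with an estimated correlation), including Tdo2 (2.19, SE 0.35), Aass (1.74) and Sdsl (1.32). The urea cycle list had a median of 1.05 with 4 higher and 1 lower (adjusted p = 0.0014, and 0.32 with an estimated correlation). Glycolysis had a median of -0.44 with 7 members lower (adjusted p = 0.00043, and 0.32 with an estimated correlation), and the hypoxia response one of -0.67 with 6 lower (adjusted p = 0.00011, and 0.082 with an estimated correlation). Interferon response transcripts had a median of -0.99 with 7 of 14 lower (adjusted p = 0.00013, and 0.47 with an estimated correlation), and -0.32 within slide 2 (0.023) and -0.33 without WT_P0 3 and 4 (0.02). Erythroid cells had a median of -0.47 with 8 of 27 lower (adjusted p = 0.001, and 0.52 with an estimated correlation), and -0.15 within slide 2 (0.12) and -0.12 without WT_P0 3 and 4 (0.19). Hepatocyte secreted proteins had a median of -0.60 (adjusted p = 1.1e-08, and 0.082 with an estimated correlation), with Fgb at -0.81, Fgg at -0.78 and Apoa2 at -0.74, but -0.02 with quantile normalization (0.43) and -0.01 from the authors' value table (0.64), where these 3 genes did not pass. The largest rises included the pancreatic transcripts Try4 (at least 118-fold), Try5 (at least 109-fold), Cpb1 (at least 40.5-fold) and Reg1 (at least 26.3-fold), bounds that rest on WT_P0 3 and 4, without which they were 18.9, 16.6, 6.57 and 5.38-fold. Try4 was at -2.85, -1.47, 2.32 and 3.94 on WT_P0 1 to 4, and the calls of Try4 (adjusted p = 0.022) and Try5 (0.016) held without WT_P0 3 and 4. The exocrine pancreas list had a median of 2.54 with 6 of 12 higher (adjusted p = 0.00011, and 0.4 with an estimated correlation), and 0.83 within slide 2 (0.072) and 0.77 without WT_P0 3 and 4 (0.092).

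The WT change passed in 19 of 42 lists, 10 up and 9 down, and in 2 with an estimated correlation. With slide as a block 2657 genes and 14 lists passed, within slide 2 1169 and 16, without WT_P0 3 and 4 2288 genes, and with the brightness covariate 0 genes. Of the 19 lists, 14 passed in the same direction with slide as a block, 13 within slide 2 and 14 without WT_P0 3 and 4. With the brightness covariate 4 did, and 2 passed the other way, interferon response (1.02) and oxidative phosphorylation (-0.23). Median centring gave 1701 higher and 1450 lower, and normexp with the 75th percentile 2407 higher and 7739 lower, with the median of all genes at -0.157 and without a call for glycolysis (0.18) or erythroid cells (0.32). The count was 2773, 2766 and 2830 without WT_E19 1, 2 and 3. The call of Reg1 ended without each of WT_E19 1, 2 and 3 and WT_P0 2, 3 and 4 (0.051 to 0.1), that of Syt10 (4.48) without WT_E19 1, WT_E19 2 or WT_P0 3 (0.051 to 0.082) and those of Reg1, Syt10 and Cpb1 without WT_P0 3 and 4. Slide as a block ended the calls of Reg1 (0.12) and Syt10 (0.11).

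In KO liver the change around birth again lowered lipid synthesis: 24 of 24 members of cholesterol synthesis (median -2.06, adjusted p = 6.7e-28, and 0.0017 with an estimated correlation) and 10 of 14 of fatty acid synthesis (median -2, adjusted p = 2.1e-13, and 0.037 with an estimated correlation) were lower. Srebf1, the transcription factor of lipid synthesis, fell by 3.22 (SE 0.16, adjusted p = 1.4e-07), Fasn by 3.29 (SE 0.19), Hmgcs1 by 3.14 (SE 0.20) and Sqle by 2.25 (SE 0.10). Gluconeogenesis rose, with a median of 0.70, 8 of 13 members higher and 1 lower (adjusted p = 3.9e-06, and 0.037 with an estimated correlation). In this list Pck1, phosphoenolpyruvate carboxykinase, rose by 3.11 (SE 0.18, adjusted p = 5.8e-07), from 4.45 ± 0.31 (n = 3) to 7.55 ± 0.26 (n = 5), Sds by 4.86 (SE 0.35) and Got1 by 3.30 (SE 0.25). PPARA targets and peroxisomal oxidation had a median of 0.84 with 7 of 20 higher and 2 lower (adjusted p = 0.00038, and 0.54 with an estimated correlation), with Pdk4 at 2.44 (SE 0.29), and was at 0.84 with slide as a block and 1.07 within slide 2. Mitochondrial fatty acid oxidation did not pass (median -0.16, 4 higher and 5 lower, adjusted p = 0.77). Glycogen metabolism had a median of -0.62 with 8 of 13 lower (adjusted p = 0.0043, and 0.25 with an estimated correlation), including Gbe1 (-1.06) and Pygl (-0.92). Glycolysis had one of -0.33 with 8 of 17 lower (adjusted p = 0.0025, and 0.52 with an estimated correlation). The urea cycle list had a median of 0.73 with 3 higher and 1 lower (adjusted p = 0.0068, and 0.52 with an estimated correlation).

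The KO change passed in 4523 genes, 1939 higher and 2584 lower, 1084 of them at least 2-fold, with 7785 at an unadjusted p under 0.05, and in 10 of 42 lists, 4 up and 6 down (3 with an estimated correlation). With slide as a block 2130 genes and 11 lists passed, and within slide 2 1092 and 12, with 9 and 8 of the 10 lists in the same direction. The medians of cholesterol synthesis and fatty acid synthesis were -2.11 and -1.80 with slide as a block and -2.06 and -1.93 within slide 2. Slide as a block ended 5 of the 34 named calls, among them that of Thrsp (-4.01; 0.051). Median centring gave 1715 higher and 1344 lower, and the count was 2303, 2495 and 2995 without KO_E19 1, 2 and 3. Both genotypes shared 998 rises, where 161.9 would be shared if the calls were independent, and 1255 falls (275.2), and 2 genes passed in opposite directions. Across genes, which are not independent replicates, the changes in the 2 genotypes correlated at r = 0.7.

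The last comparison asks whether the KO effect differed between the ages. No gene passed in limma (smallest adjusted p = 0.12), with 2124 genes at an unadjusted p under 0.05 where chance gives 1132, and 0 with slide as a block or within slide 2. With array weights 75 genes passed, and with a trend and robust fit 13. The 5 smallest p-values, given as not passing, belonged to Tmem141 (-1.16, SE 0.18), Wnt9b (-1.52, SE 0.26), Pla2g6 (-1.32, SE 0.23), Serpina1c (0.71, SE 0.12) and Pfkfb2 (0.99, SE 0.17). Among lists, 15 of 42 passed camera, 6 up and 9 down, and 0 with an estimated correlation (smallest adjusted p = 0.35). The difference was -0.49 for mitochondrial fatty acid oxidation (adjusted p = 4.8e-08, and 0.41 with an estimated correlation) and 0.34 for erythroid cells (adjusted p = 6.5e-08, and 0.43 with an estimated correlation). With slide as a block 15 lists passed, and within slide 2 4, where mitochondrial fatty acid oxidation was at -0.14 (0.61). With the brightness covariate these lists were at 0.01 and -0.12 and did not pass.

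All 5 genes that fell at E19.5 also fell at P0, where 0.2 would be shared if the calls were independent, and 0 of the 3 that rose did so again (0.1). The 5 include Mirg, the host of the deleted cluster, and the long noncoding RNA probe beside it, for which independence is no fair reference. Across genes, the KO effects at the 2 ages correlated at r = 0.21 (permutation p = 0.029, two-sided, 74 of 2520 regroupings of genotype within age, with the possible P0 pairs left aside, at least as far from 0). This r was 0.121 within slide 2 and 0.075 with normexp and the 75th percentile, and turned to -0.341 with the brightness covariate. The KO effect at P0 and the WT change around birth share the WT_P0 arrays, and r between them across genes was -0.3, where unchanged simulated groups gave -0.49. Their covariance was -0.07, where simulated groups gave -0.031, a difference of -0.039. With the WT_P0 arrays split between the contrasts, r averaged -0.09 over 6 splits (-0.19 to 0.1) and the covariance -0.024 (-0.047 to 0.032). As the sign turned among the splits, whether the 2 opposed each other beyond the shared arrays stays open. Of the genes lower in KO_P0, 236 had risen in WT (89.3 if the calls were independent, which leaves out the shared arrays) and 84 had fallen (114), and of those higher, 114 had fallen (55.5) and 53 had risen (43.5).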

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

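The tests of B lineage cells, array brightness and a strain segment for the heavy chain pattern, of the share of hepatocytes for the oxidation pattern, and both tests of the pancreas pattern were chosen only after the results were seen, as were the fits without WT_P0 3 and 4 and with the brightness covariate. Of 266 groups of 4 or 5 arrays, 20 had 1 array far from the others, where chance alone marks about 1 in 20 groups, or 13. The value given is the gap to the nearest array as a share of the group's range.

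In the immunoglobulin heavy chain interval from 114729640 to 117298954 of mm9 chromosome 12, 33 of 37 heavy chain transcripts had positive KO minus WT differences at E19.5 and 15 had an unadjusted p under 0.01, against 0 at P0. Their mean level was -4.23 ± 0.13 (n = 3) in WT_E19 and -3.5 ± 0.1 (n = 3) in KO_E19, a difference of 0.73 (exact p = 0.1, the smallest this design allows), and the difference at P0 was -0.02 (exact p = 0.9). The tables argue against more B lineage cells, since the median of that list was 0.02 (SD 0.16) at E19.5 with its most abundant genes Vpreb3 at 4.4 and 4.47 and Cd79b at 4.13 and 4.06 in WT_E19 and KO_E19. They argue against brighter arrays only as far as age does not matter, since the still brighter WT_P0 arrays, which lay -0.64 from KO_E19, also differ in age. A segment of another strain beside the deletion stays open. The excess of other distal genes that differed depended on where the segment was taken to start (exact one-sided p from 0.0062 to 0.22 over 7 starts, 4 of them under 0.05). All 4 counted a dim transcript and Serpina1c (10.28 in WT_E19) and Serpina1e (10.25). These serpins were as bright as Fgb (10.17 in WT_E19), so the differences of both may follow brightness. The other starts counted only Vipr2 and Wdr60. However, a segment shared by all KO pups would also be seen at P0, and a direct effect of genotype stays open as untested.

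The mitochondrial fatty acid oxidation list was lower in KO_P0, with a median of -0.56 and a difference between array medians of -0.51 (SE 0.11). The passes below are at camera's preset correlation, and with an estimated one 0 of the 21 lists called at P0 passed. Pancreatic tissue in WT_P0 3 and 4 is argued against as the whole cause: without these arrays the list median was -0.32 and still passed, with a difference between array medians of -0.34 (SE 0.1). That fit set WT_P0 arrays of slide 2 against KO_P0 arrays of slides 2 and 3, so it mixes genotype with slide. The argument therefore holds only as far as slide does not matter. Within slide 2, which holds neither pancreatic array, the list was lower as well, at -0.22. An equal shift of all arrays of a slide is argued against as the whole cause by -0.56 with slide as a block (array medians -0.52, SE 0.11). The fall was -0.22 within slide 2, less than the planned rule asked of each slide, and -0.82 within slide 3. An effect that differs between the slides therefore stays open. Array brightness stays open, since with it as a covariate the list median was -0.32 and still passed, but the difference between array medians only -0.24 (SE 0.09). A lower share of hepatocytes stays open too, since the hepatocyte secreted proteins (0.16) rose by only 0.34 per unit of log2 brightness over all arrays, a slope that change with age also enters, and the lists of hepatocyte transcription factors (-0.34) and erythroid cells (0.41) go with such a share. At P0 the brightness of the genotypes overlapped only between WT_P0 2 (9.23) and KO_P0 4 (9.33), and an effect of genotype stays open.

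Exocrine pancreas transcripts were higher in WT_P0 than in KO_P0. For 11 of the 12 measured members the 2 highest P0 arrays were WT_P0 3 and WT_P0 4, where Ctrb1 was at 4.06 and 5.22 and Amy2a5 at 4.96 and 6.3. Only Cela1 and Amy2a5 were above 0 on every array. A difference of genotype is argued against by slide 2, which holds neither array and where the list median was -0.12. A candidate explanation is pancreatic tissue taken with these 2 livers, and smaller amounts on other arrays, such as KO_P0 3 (-1.03), are not excluded.

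KO_P0 5 was highest for Ckm at -2.62 against -5.48 or lower (0.81) and lowest for Fgf21 at -6.78 against -3.29 or higher (0.86). It was also highest for Ifit3 at 2.62 against 1.82 or lower (0.74), Insig1 at -0.53 against -1.15 (0.72), Pnpla5 at -5.45 against -6.86 (0.81), Scd1 at 2.86 against 2.01 (0.87), Scd2 at 3.86 against 3.15 (0.78) and Mirg at -0.41 against -1.34 (0.8). KO_P0 2 was lowest for 6430411K18Rik at -7.05 against -5.44 (0.9) and highest for Itgae at -0.45 against -1 (0.81). Pnpla5 and 6430411K18Rik were not well above background on any KO_P0 array, so these 2 gaps are read no further. KO_P0 1 was highest for Pla2g6 at 1.81 against 1.24 (0.74). KO_P0 4 was lowest for the mean of the heavy chain transcripts at -4.6 against -4.14 (0.77). WT_P0 1 was lowest for Cidec at -0.24 against 0.98 (0.87) and Hmgcs1 at 4.34 against 5.04 (0.86). WT_P0 2 was lowest for Mt1 at 7.14 against 8.16 (0.88) and highest for the median of the adrenal cortex list at 2.02 against -1.07 (0.96). WT_P0 4 was lowest for Kif11 at 0.21 against 0.63 (0.86), Meg3 at 5.17 against 5.43 (0.85) and Tsc22d3 at 1.73 against 2.26 (0.87).

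The KO effect differed between the ages by camera in 15 lists, 0 of them with an estimated correlation (smallest adjusted p = 0.35), while no gene passed in limma (2124 at an unadjusted p under 0.05). The effect at P0 was lower than at E19.5 for mitochondrial fatty acid oxidation (-0.49, adjusted p = 4.8e-08), PPARA targets and peroxisomal oxidation (-0.62, 0.0014), cytochrome P450 drug metabolism (-0.32, 0.003), amino acid catabolism (-0.36, 0.0033), oxidative phosphorylation (-0.14, 0.0035). It was also lower for ketone body synthesis (-0.34, 0.0037), bile acid synthesis and transport (-0.47, 0.0037), exocrine pancreas (-2.13, 0.0037) and unfolded protein response (-0.42, 0.0073). It was higher for hepatocyte secreted proteins (0.36, 4.8e-08), erythroid cells (0.34, 6.5e-08), glucocorticoid and cAMP response (0.47, 0.00017), cell cycle (0.21, 0.00068), integrated stress response (0.34, 0.0044) and interferon response (0.47, 0.024). Of the 15 lists, 3 passed in the same direction within slide 2, 5 without WT_P0 3 and 4 and 0 with the brightness covariate, where 3 passed the other way. For hepatocyte secreted proteins the difference was -0.01 with quantile normalization.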

How the results depend on the processing

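The fits without WT_P0 3 and 4 (pancreatic arrays), without the 5 arrays with muscle or adrenal transcripts and with the brightness covariate were chosen after the data were seen; all others were planned. Brightness, slide and transcripts typical of neighbouring organs differ with the groups. Of the variance of brightness 89.8% lay between groups, so its slope rests on small differences within them. Calls that ended or turned with this covariate therefore cannot tell brightness from group. With the brightness covariate 1 of 4 named calls at E19.5, 2 of 34 at P0, 0 of 32 in WT and 29 of 34 in KO held, and with slide as a block 3, 33, 28 and 29. Under all alternatives 0 of 4, 1 of 34, 0 of 32 and 24 of 34 named calls held. Slide 3 alone gives KO against WT at P0 only. Single probes, fold limits, array weights, other limma settings and the plain two-group test were run on genes and not on lists, and a contrast's own groups and the plain two-group test cannot give the difference of effects. Dim genes are limited by signal over background, since 53.1% to 65.7% of probes were above it. Cholesterol synthesis and fatty acid synthesis passed in the same direction over age in both genotypes under every scaling, slide and array setting run. With the brightness covariate, however, no named gene of either list kept its call in WT. A fold limit lowers the count by its construction, while fits with fewer arrays gave lower counts in some cases and higher ones in others, and for these and the other changes the cause was not tested.

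KO against WT at E19.5 gave 8 genes, and 14 with normexp and quantile, 13 from the authors' value table, 16 with every probe by itself. It gave 1 within slide 2, 4 with the replicate block, 5 with only the groups of the contrast, 68 with array weights, 0 in a plain two-group test (1444 at an unadjusted p under 0.05), 4 without the 5 muscle or adrenal arrays and 2 with the brightness covariate. Without 1 array it gave 3 to 10. The lists that passed, whichever they were, numbered 14, and 5 with normexp and the 75th percentile, 6 with no dim-probe filter, 0 with an estimated correlation and 1 with fry, and 8 to 16 without 1 array (8 without WT_E19 1 and 9 without KO_E19 1). Of the 14 themselves, 5 still passed in the same direction with normexp and the 75th percentile, 6 with no dim-probe filter, 9 within slide 2, 8 with the brightness covariate and 7 without WT_E19 1.

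KO against WT at P0 gave 1591 genes, and 614 with median centring, 788 with no dim-probe filter, 2 within slide 2, 861 within slide 3. It gave 433 with the replicate block, 280 with only the groups of the contrast, 1024 with the sex covariate, 220 with treat, 371 at 2-fold, 36 in a plain two-group test, 168 without the pancreatic arrays and 3 with the brightness covariate. Without 1 array it gave 585 to 2349 (585 without WT_P0 3). The lists that passed numbered 21, and 12 within slide 2, 0 with an estimated correlation and 11 with the brightness covariate, and 18 to 22 without 1 array. Of the 21 themselves, 10 still passed in the same direction within slide 2, 9 with the brightness covariate and 13 without the pancreatic arrays.

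P0 against E19.5 in WT gave 4301 genes, and 10146 with normexp and the 75th percentile, 6578 with every probe by itself, 2657 with slide as a block, 1169 within slide 2. It gave 2554 with only the groups of the contrast, 1251 with treat, 1119 at 2-fold, 1639 in a plain two-group test, 2288 without the pancreatic arrays and 0 with the brightness covariate. Without 1 array it gave 2766 to 4932 (2766 without WT_E19 2). The lists that passed numbered 19, and 2 with an estimated correlation and 8 with the brightness covariate, and 16 to 22 without 1 array. Of the 19 themselves, 4 still passed in the same direction and 2 in the other with the brightness covariate, and 13 in the same direction within slide 2 and 14 without the pancreatic arrays. With the brightness covariate, which largely follows the groups, the sign of 6 named genes in WT turned: Thrsp 0.23, Lrrc24 0.57, Scd1 0.43, Dio3os 0.54, Syt10 -4.33 and Cpb1 -0.26. Fgb and Apoa2 turned to 0.01 and 0.01 with normexp and quantile and to 0.01 and 0.02 from the authors' value table.

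P0 against E19.5 in KO gave 4523 genes, and 2130 with slide as a block, 1092 within slide 2, 7461 with array weights, 1228 with treat, 1084 at 2-fold and 2387 with the brightness covariate. Without 1 array it gave 2303 to 4972 (2303 without KO_E19 1). The lists that passed numbered 10, and 18 with no dim-probe filter, 3 with an estimated correlation, 18 with fry and 16 without the muscle or adrenal arrays, and 9 to 12 without 1 array. Of the 10 themselves, 10 still passed in the same direction with no dim-probe filter, 10 with fry, 9 without the muscle or adrenal arrays, 8 within slide 2 and 8 with the brightness covariate.

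The difference of the KO effect gave 0 genes in limma (2124 at an unadjusted p under 0.05), and 5 with normexp and the 75th percentile, 1 with normexp and quantile, 1 from the authors' value table, 1 with the random replicate block. It gave 13 with trend and robust, 75 with array weights, 1 with the sex covariate, 2 without the pancreatic arrays and 42 without the muscle or adrenal arrays. Without 1 array it gave 0 to 18 (18 without KO_P0 1 and 3 without WT_P0 1). The lists that passed numbered 15, and 4 within slide 2, 0 with an estimated correlation, 1 with fry, 5 without the pancreatic arrays and 6 with the brightness covariate, and 11 to 17 without 1 array. Of the 15 themselves, 3 still passed in the same direction within slide 2, 5 without the pancreatic arrays and 0 with the brightness covariate, where 3 passed the other way.

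The correlation of the KO effects at both ages, 0.212, was 0.075 with normexp and the 75th percentile, 0.063 with no dim-probe filter, 0.121 within slide 2, 0.11 without the muscle or adrenal arrays and -0.341 with the brightness covariate, and 0.116 to 0.279 without 1 array. The correlation of the KO effect at P0 with the WT change, -0.299, was -0.376 with no dim-probe filter, -0.613 without the muscle or adrenal arrays and -0.546 with the brightness covariate, and -0.437 to -0.241 without 1 array. Without the muscle or adrenal arrays, WT_P0 3 was the only WT_P0 array in both correlations. The count of domain genes past the threshold, 3 over both ages, was 1 with the brightness covariate and 3 to 3 without 1 array.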

Other observations

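The regroupings below were planned, and where the slides fall among them was looked at after they were seen. At E19.5 the granulocytes list had a median of 0.19 (adjusted p = 0.00074, and 0.6 with an estimated correlation) and did not pass within slide 2 (median 0.16, adjusted p = 0.16). The stellate and mesenchymal cells list had a median of -0.18 (adjusted p = 0.00087, and 0.36 with an estimated correlation) and did not pass without WT_E19 1 (median -0.04, adjusted p = 0.11). At P0 the same list had a median of -0.36 with 1 of 14 members lower and 4 when adjusted over the list alone (adjusted p = 0.0032, and 0.31 with an estimated correlation), and did not pass within slide 2 (median -0.16, adjusted p = 0.055). Megakaryocytes and platelets (-0.13, adjusted p = 0.11), granulocytes (0.18, 0.12), macrophages and Kupffer cells (0.06, 0.21), cholangiocytes (-0.28, 0.24) and endothelial cells (0.04, 0.99) did not pass at P0, and neither did T and NK cells (-0.28, 0.13). Mast cells and basophils passed with a median of -0.26 and 1 of 7 members lower, 2 when adjusted over the list alone (adjusted p = 0.042, and 0.22 with an estimated correlation). The median of that list was -1.08 to -0.5 on the KO_P0 arrays and -0.25 to 0.21 on the WT_P0 arrays, and the call ended within slide 2 (0.19), within slide 3 (0.067), without WT_P0 3 and 4 (0.32) and with the brightness covariate (0.36). From E19.5 to P0 in WT, stellate and mesenchymal cells had a median of 0.33 with 2 of 14 members higher and 6 when adjusted over the list alone (adjusted p = 0.0053, and 0.32 with an estimated correlation).

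Several metabolic and stress lists did not pass between the genotypes at P0. Fatty acid synthesis had a median of -0.06 with 1 of 14 members higher and 3 lower (adjusted p = 0.36), glycogen metabolism one of -0.27 with 1 higher and 1 lower (0.11), glycolysis one of -0.02 (0.97) and the urea cycle one of 0 (0.93). The hypoxia response list had 3 of 14 members higher (median 0.06, adjusted p = 0.24), and the NRF2 antioxidant response list 3 of 11 lower (median -0.01, adjusted p = 0.16). Fetal liver genes had a median of 0.20 with 2 of 13 higher and 1 lower (adjusted p = 0.21), and other imprinted genes one of -0.12 with 1 of 23 higher and 1 lower (0.72). In WT liver the circadian clock list had a median of 0.44 from E19.5 to P0, with 5 of 13 members higher and 1 lower (adjusted p = 0.071).

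Arrays were regrouped to ask whether chance groupings give as many calls. At P0, with the replicate pairs left aside, 1 of 100 regroupings, the real one, of the 126 possible gave as many genes (1591, with 1368 the highest of the others) and 3 of 100 as many lists (21, with 22 the highest of the others), so chance can be excluded for both only as far as the pairs do not matter. The regrouping with 1368 is the real one with KO_P0 1 moved to the WT side. One along the slides (WT_P0 1 and 2 with KO_P0 1 and 2 against the rest) gave 1088 genes, which points to a structure of the arrays by slide; with slide as a block 1961 genes passed, within slide 2 2 and within slide 3 861. The 16 regroupings that part all 4 possible replicate pairs are too few for a share under 0.05. Of these 16, 1 gave as many genes (1591, with 4 the highest of the others) and 2 as many lists (21, with 22).

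For the change from E19.5 to P0 chance can be excluded for the genes only as far as slide does not matter, with 1 of 35 regroupings in WT (4301, with 2743 the highest of the others) and 1 of 56 in KO (4523, with 1096). The regroupings left the slides aside, although slide 1 held E19.5 arrays only and slide 3 P0 arrays only. Chance cannot be excluded for the lists, with 6 of 35 in WT (19, with 24) and 9 of 56 in KO (10, with 16). The regrouping with 1096 genes set the KO_P0 arrays of slide 3 against the rest. For the difference of the KO effect the real grouping gave 0 genes (3 the highest of the others). Every regrouping gives at least as many, so for the genes this test cannot tell anything about chance. For the lists chance cannot be excluded, with 14 of 100 regroupings of the 2520 possible (15, with 20). At E19.5 the 10 possible regroupings are too few for a share under 0.05, with 1 of 10 giving as many genes (8, with 1 the highest of the others) and 1 of 10 as many lists (14, with 7).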
